A study of Rattus norvegicus with 12 samples.

How the data were processed

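Gene expression was measured in 12 kidneys of 36-day-old rats of the PKD/Mhm line on Affymetrix arrays, 1 array per kidney. The samples formed 4 groups of 3, wild type males, wild type females, affected heterozygous males and affected heterozygous females, and the labels call the 3 arrays of a group biological replicates. Per the labels' protocols, the left kidney was frozen in liquid nitrogen, total RNA was taken up with Trizol, and biotin-labelled cRNA was made by the manufacturer's standard procedure.

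The deposited table holds 1 signal value per probe set and array on a log2 scale, for 15923 probe sets. The log base and the method with which the authors summarised and normalized the arrays are not stated in the labels. The base was taken from the values, which run from 5.449 to 14.15. Read as natural logarithms, the highest would exceed the range of a 16-bit scanner 21.4-fold. The array medians lay between 6.254 and 6.292, a range of 0.038, below the limit of 0.2 set for scaling again, so the deposited values were used as given. Of all values 34% lay under 6, in a dense floor, so changes of weakly expressed genes are compressed. No pair of arrays was identical.

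The 57 control probe sets were set aside and 15866 were tested. Gene symbols came from the platform annotation, matched through the Entrez identifier for 12748 probe sets and kept as given there for 35. In all 12783 probe sets named 1 gene, 312 named several and 2771 had no symbol in the annotation used here. The named probe sets covered 10411 different genes. A gene with several probe sets is reported by probe set. Genes are named by symbol, and the identifiers of their probe sets are not printed. No genome build was used, so no positions are given.

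A linear model with 1 mean per group was fitted to all 12 arrays with limma (version 3.58.1, R 4.3.3; empirical Bayes prior of 1.63 degrees of freedom), so that the 4 groups shared 1 estimate of the spread. Its moderated test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 15866 probe sets of a comparison. A probe set was called at an adjusted p under 0.05. The comparisons were affected minus wild type in males and in females, male minus female in wild type and in affected rats, the difference between the genotype effects of the sexes (the interaction), the genotype effect averaged over the sexes and the sex effect averaged over the genotypes. Every p printed for a gene is an adjusted p from limma unless it is called unadjusted. The number of arrays limits the precision of every value.

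Gene lists for 35 processes, cell types and hormone-related groups were written before the data were examined, as were the design, the alternatives and the rule for the genes named. They hold 995 genes, of which 796 were measured. Of these lists 34 had at least 4 measured genes and were tested with camera, limma's competitive gene set test, at a preset correlation between genes of 0.01, with the probe set of highest mean signal standing for each gene and the p-values adjusted over the lists of a comparison. Each test was repeated with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance in one direction. Counts of list members past the threshold are given after adjustment over all probe sets and, where named so, adjusted over the list alone.

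The genes named are, for each comparison of 2 groups, up to 8 with the largest rise and up to 8 with the largest fall among called probe sets that name 1 gene and whose groups do not overlap. For the interaction they are the 5 of smallest p, as values. From each list come up to 4 members of largest change past the threshold, or the 2 of smallest p as values. Also named are Anks6, the gene mutated in this line, the Y-linked genes and Xist. Anks6 is not among the genes named in the annotation and was not analysed here, so the genotype labels were not checked against it.

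Rats of a sex and genotype share replicate numbers with those of the other groups. Deviations from the group means of same-numbered males and females correlated at 0.133 to 0.143 in wild type and at 0.374 to 0.543 in affected rats, over 0.1 in each of the 6 pairs. Males and females of different numbers reached at most 0.0645 in wild type and -0.0639 in affected rats. Wild type and affected males of different numbers reached 0.27, so a value over 0.1 does not by itself mark a pair, least of all in wild type. The numbers may thus pair the sexes within a genotype, which these values do not settle. The labels give no source of such a pairing. The fit with the number as a block within genotype is therefore an alternative for the comparisons of the sexes and the interaction, and the mean of each pair for the averaged genotype effect.

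The alternatives were quantile normalization, arrays centred on their medians, leaving out the 40% of probe sets of lowest mean, a trend of the variance with signal, array weights, the replicate number as a block, a floor at the 20th percentile (5.827), a test against a 1.2-fold change (treat), fits on the 6 arrays of a comparison alone, and each array left out in turn. The block within genotype, the means of pairs and a covariate for RNA quality, the difference between the 3' and 5' beta-actin control signals of an array, were added after seeing the data. For the lists, the mean over a gene's probe sets was also used. The code was tested on simulated data with the spread of the 15866 probe sets. Values were drawn independently for each probe set and array, without correlation between genes or pairing of arrays. The changed probe sets were taken from those above the median signal, so the shares called say nothing on weakly expressed genes. Of 100 probe sets changed by 0.5 in affected males 85 were called, of 100 changed by 1 there were 96, and of 15666 unchanged probe sets 12 were called in that comparison. The simulated interaction called 66% of the changes of 0.5 that were made in males alone and 94% of those of 1. Smaller differences between the sexes were not simulated, and each probe set had the same spread in all groups. The shares thus say nothing on the power for smaller differences. In males, a list of 30 genes shifted by 0.2 reached an adjusted p of 2.1e-48 and 0 of 30 random lists were called, over 10411 genes. Because these simulated genes do not vary together, this does not test the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.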

Results

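Kidney gene expression was compared between male and female rats of the PKD/Mhm line, an inbred line with an inherited dominant cystic kidney disease. Total RNA of the left kidney was measured at 36 days of age in 3 wild type males, 3 wild type females, 3 affected heterozygous males and 3 affected heterozygous females, each on its own array. The study asked how expression depends on sex in affected rats and in their wild type littermates. Values are log2 signals, changes are differences of group means on that scale, and the number of arrays limits the precision. Xist, the transcript that coats the inactive X chromosome, stood at 9.58 ± 0.26 in wild type females and 9.10 ± 0.05 in affected females (SD, n = 3). In males it lay near the floor of the scale, at 5.99 ± 0.03 in affected males (SD, n = 3), with male minus female values of -3.58 in wild type and -3.11 in affected rats, so that no array went against its sex label. The Y-linked probe sets of Sry and Rps4y2 lay at the floor of the scale in both sexes, with male minus female values of -0.02 and 0.06 in wild type, and checked no label. The difference between 3' and 5' beta-actin control signals, a sign of RNA quality, was 0.94 ± 0.06 in wild type males, 0.98 ± 0.22 in wild type females, 0.89 ± 0.09 in affected males and 0.88 ± 0.09 in affected females (SD, n = 3). Wild type female replicate 1 stood apart at 1.23. The first principal component held 40.3% of the variance, and on it affected male replicate 3 lay at 20.45, with the other affected males at 10.08 and 11.87.

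Affected males differed from wild type males first in genes of tubular injury. Clu, which encodes the chaperone clusterin secreted by stressed epithelium, rose from 7.62 ± 0.30 to 11.64 ± 0.45 (SD, n = 3), a 16.2-fold change with an SE of 0.31 and an adjusted p of 0.000606. Havcr1, the kidney injury molecule shed by damaged proximal tubule, rose at least 5.77-fold from 6.09 ± 0.08, near the floor of the scale, to 8.62 ± 1.06 (adjusted p = 0.00965). Spp1, encoding osteopontin, an adhesive glycoprotein of injured tubules, rose 5.7-fold from 10.93 ± 0.25 to 13.44 ± 0.13 (adjusted p = 0.000606). Cp, encoding the copper carrier ceruloplasmin, rose 3.12-fold (SE 0.11, adjusted p = 0.000606). Of the 28 measured genes of tubular injury and dedifferentiation 17 rose and 0 fell, 21 rose when adjusted over the list alone, and the median change was 0.61. Camera gave the list an adjusted p of 1.6e-15, with adjusted p = 0.0909 with an estimated correlation. A second Clu probe set, at a change of 0.04, did not pass the test.

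Genes of the extracellular matrix rose together in affected males, 29 of 44 with 0 that fell, and 40 when adjusted over the list alone, with a median of 0.60. The list's camera adjusted p was 6.8e-23, and adjusted p = 0.0909 with an estimated correlation. Fn1, encoding fibronectin, rose 2.77-fold from 9.34 ± 0.41 to 10.81 ± 0.41 (SD, n = 3, adjusted p = 0.0121). Dcn, encoding the collagen-binding proteoglycan decorin, and Mgp, encoding a matrix inhibitor of calcification, each rose 2.73-fold (adjusted p = 0.00183 and 0.00146). Tagln, encoding the actin-binding protein transgelin of smooth muscle and myofibroblasts, rose 3.06-fold (adjusted p = 0.0155). Without wild type male replicate 2 its adjusted p was 0.0538, and without affected male replicate 3 it was 0.0531.

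Genes of the leukocyte, antigen presentation and complement lists rose in affected males too. Of 27 genes of macrophages and other leukocytes 12 rose, 17 when adjusted over the list alone, with a median of 0.20 and a camera adjusted p of 3.25e-11 (adjusted p = 0.0909 with an estimated correlation). Fcer1g, the signalling chain of Fc receptors on myeloid cells, rose 1.81-fold from 8.22 ± 0.07 to 9.07 ± 0.10 (SD, n = 3, adjusted p = 0.000666). C1qc, a complement chain made largely by macrophages, rose 1.98-fold (adjusted p = 0.00393), and Arpc1b, an actin-nucleating subunit abundant in blood cells, rose 1.89-fold (adjusted p = 0.0022). The class II antigen-presenting genes RT1-Db1 and RT1-Bb rose 1.79-fold and 1.78-fold (adjusted p = 0.00705 and 0.0102), and Ifitm1, an interferon-induced membrane protein, rose 2.05-fold (adjusted p = 0.0106). A second probe set of RT1-Db1, at 0.06, and one of RT1-Bb, without a change, did not pass. In the list of antigen presentation and interferon response 13 of 34 rose, 20 when adjusted over the list alone, with a median of 0.22 and a camera adjusted p of 1.59e-09 (adjusted p = 0.0909 with an estimated correlation). Serping1, the inhibitor of complement C1, rose 2.11-fold (adjusted p = 0.0071). Of 23 complement and coagulation genes 9 rose, 14 when adjusted over the list alone, with a median of 0.20 and a camera adjusted p of 2.12e-06 (adjusted p = 0.0909 with an estimated correlation). Tnfrsf1a, a receptor of tumour necrosis factor, rose 2.14-fold (adjusted p = 0.00904), Stat3, a transcription factor of cytokine signalling, 1.57-fold (adjusted p = 0.00353), and Icam1, a leukocyte adhesion molecule, 1.39-fold (adjusted p = 0.00219). These were among 5 of 27 chemokine and cytokine genes that rose, 8 when adjusted over the list alone, with a median of 0.04 and a camera adjusted p of 0.00679 (adjusted p = 0.193 with an estimated correlation).

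Cell cycle and immediate early genes were among those that rose. Cks2, a cofactor of cyclin-dependent kinases, rose by 0.35 (SE 0.05, adjusted p = 0.00349). In the cell cycle list 6 of 31 genes rose, 17 when adjusted over the list alone, with a median of 0.12 and a camera adjusted p of 1.11e-06 (adjusted p = 0.205 with an estimated correlation). The transcription factor genes Klf6 and Myc rose by 0.39 and 0.26 (adjusted p = 0.00707 and 0.00267), and a second Klf6 probe set, at 0.15, did not pass. With 1 further gene they made 3 of 18 immediate early genes that rose, 6 when adjusted over the list alone, at a median of 0.06 (camera adjusted p = 0.00662; adjusted p = 0.147 with an estimated correlation). That call ended without the dimmest 40% of probe sets, at an adjusted p of 0.144. Single genes of other lists changed as well. Igfbp1, a binding protein of insulin-like growth factors, rose 2.09-fold (adjusted p = 0.00219). Ldha, the lactate dehydrogenase of glycolysis, rose 1.5-fold (adjusted p = 0.00708), and Sfrp2, a secreted Wnt antagonist, fell by 0.62 (adjusted p = 0.00858), in lists that did not pass (camera adjusted p = 0.36 and 0.242).

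Transport genes of the tubule were on the lower side in affected males. In the proximal tubule list 5 of 52 genes fell and 1 rose, 13 fell and 1 rose when adjusted over the list alone, and the median was -0.20 (camera adjusted p = 2.83e-11; adjusted p = 0.135 with an estimated correlation; fry 0.0513). Slco1a1, an organic anion transporter of the male proximal tubule, fell from 9.10 ± 0.32 to 7.94 ± 0.46 (SD, n = 3), a 2.25-fold change with an adjusted p of 0.0201. Its call ended without wild type male replicate 1 or 2, with adjusted p up to 0.0879. Mep1b, a brush border protease, fell 1.57-fold (SE 0.09, adjusted p = 0.00525). The proximal tubule member that rose, Slc34a2, a phosphate cotransporter best known from lung and intestine, was 2.54-fold higher (adjusted p = 0.00684). Egf, a growth factor made by the distal nephron, fell from 11.19 ± 0.01 to 10.56 ± 0.27 (SD, n = 3, adjusted p = 0.0121; 0.0512 without wild type male replicate 2). Cldn19, a tight junction claudin of the thick ascending limb, rose 1.95-fold (adjusted p = 0.0022). These were the 2 called members of 20 genes of the thick ascending limb and distal convoluted tubule, also when adjusted over the list alone, and the median was -0.18 (camera adjusted p = 3.67e-05; adjusted p = 0.0909 with an estimated correlation). Slc26a4, which encodes the anion exchanger pendrin of intercalated cells, fell by 0.46 (adjusted p = 0.0106; 0.0511 without wild type male replicate 2). It was 1 of 2 genes that fell among 18 of the collecting duct, 2 also when adjusted over the list alone, at a median of -0.06 (camera adjusted p = 0.00136; adjusted p = 0.0909 with an estimated correlation).

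Genes of fatty acid oxidation and amino acid metabolism were among those that fell. In the list of fatty acid oxidation 4 of 35 genes fell, 8 when adjusted over the list alone, with a median of -0.21 and a camera adjusted p of 3.64e-11 (adjusted p = 0.111 with an estimated correlation). Slc25a20, the carnitine carrier of the mitochondrial membrane, fell by 0.30 (adjusted p = 0.00866), and Acadm, a dehydrogenase of medium-chain fatty acids, by 0.32 (adjusted p = 0.0125; 0.0512 without wild type male replicate 2). Of 30 genes of amino acid and glycine metabolism 3 fell, 10 when adjusted over the list alone, with a median of -0.19 and a camera adjusted p of 7.24e-11 (adjusted p = 0.0909 with an estimated correlation). Adh1c, an alcohol dehydrogenase, fell 1.82-fold from 9.12 ± 0.11 to 8.26 ± 0.04 (SD, n = 3, adjusted p = 0.0022). Among 51 genes of cytochrome P450 and conjugating enzymes 1 fell and 1 rose, 2 and 1 when adjusted over the list alone, at a median of -0.02 (camera adjusted p = 0.000775; adjusted p = 0.0909 with an estimated correlation). In the list of oxidative phosphorylation 2 of 48 genes fell, 0 when adjusted over the list alone, at a median of -0.03 (camera adjusted p = 0.00679; adjusted p = 0.507 with an estimated correlation). Its call ended with fry (0.567) and without wild type male replicate 3 (0.0634) or affected male replicate 2 (0.222). Of 23 genes of the tricarboxylic acid cycle and gluconeogenesis 0 passed the test, also when adjusted over the list alone, at a median of -0.09 (camera adjusted p = 0.00679; adjusted p = 0.507 with an estimated correlation). That call ended with fry (0.45) and without affected male replicate 3 (0.0727).

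Slc22a24, an organic anion transporter, fell by 0.62 (adjusted p = 0.00607) in the list of genes known as higher in female rodent kidney. There 2 of 11 genes fell, 5 when adjusted over the list alone, with a median of -0.28 and a camera adjusted p of 6.26e-05 (adjusted p = 0.0909 with an estimated correlation). Of 33 genes of steroid and growth hormone signalling 2 rose and 2 fell, 3 and 3 when adjusted over the list alone, at a median of -0.05 (camera adjusted p = 0.0401; adjusted p = 0.0909 with an estimated correlation). Fry (0.259) and quantile normalization (0.107) ended that call, as did leaving out the dimmest 40% of probe sets (0.109), wild type male replicate 1 (0.0727) or 3 (0.0533), or affected male replicate 2 (0.0576) or 3 (0.0587). The list of genes known as higher in male rodent kidney did not pass (camera adjusted p = 0.0603), with Slco1a1 lower and Aoc1, a diamine oxidase, higher.

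Over all 15866 probe sets limma called 878 in males, 753 higher and 125 lower in affected rats, from 618 and 110 different genes. In each call all 3 values of one group lay above all 3 of the other, as in 24.8% of all probe sets, where chance gives 10%. The change exceeded 2-fold in 35 calls, 34 of them higher. Quantile normalization gave 497 higher and 284 lower calls, so that the excess of higher calls was smaller. The count was 451, 307 and 501 without wild type male replicates 1, 2 and 3 and 500 without affected male replicate 3. With an estimated correlation 0 of the 18 lists that camera called stayed called, and this was so in every comparison.

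**Figure D1:**
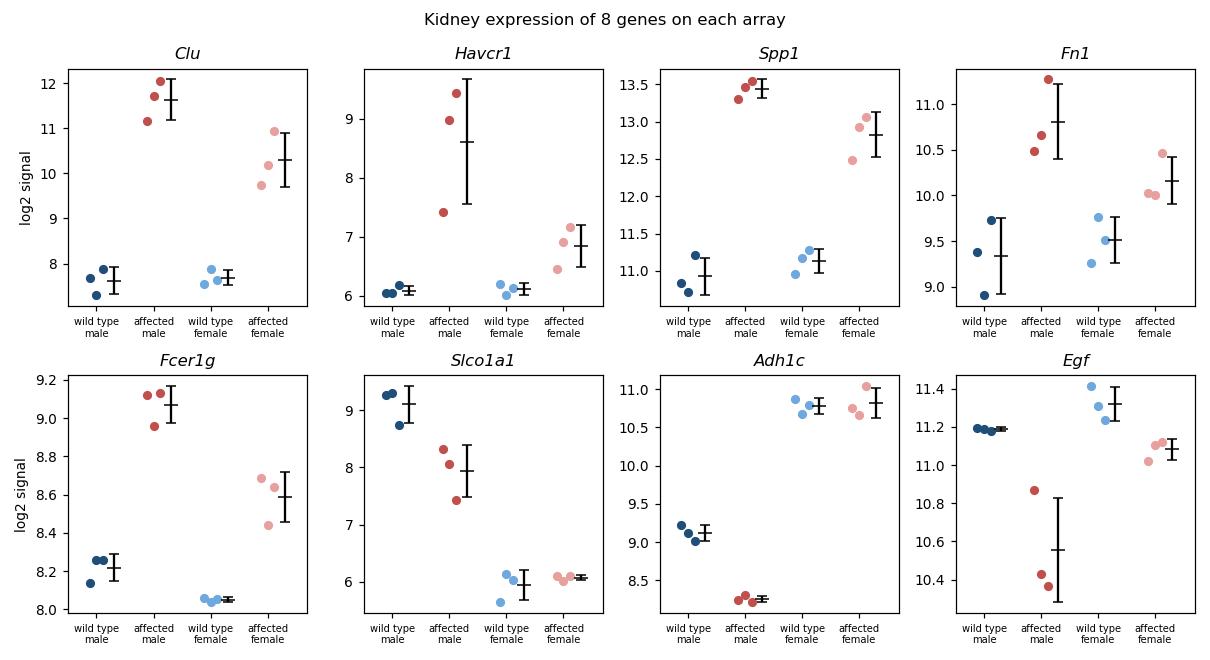
Log2 signal of 8 genes on each of the 12 arrays, by group, with points for arrays, ticks for group means and bars for ± 1 SD (n = 3). Clu stood at 7.62 in wild type males and 11.64 in affected males, and Slco1a1 at 9.10 and 7.94.

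Affected females differed from wild type females in a few injury genes that had also risen in males. Spp1 rose 3.22-fold from 11.14 ± 0.16 to 12.82 ± 0.30 (SD, n = 3), with an SE of 0.17 and an adjusted p of 0.0281. Clu rose 6.09-fold from 7.69 ± 0.17 to 10.29 ± 0.60 (SD, n = 3, adjusted p = 0.0292), and Cp 1.92-fold (adjusted p = 0.0292). Fcer1g rose 1.45-fold from 8.05 ± 0.01 to 8.59 ± 0.13 (SD, n = 3, adjusted p = 0.0292). Plin2, a coat protein of lipid droplets, rose by 0.35 and Vkorc1, the vitamin K epoxide reductase, by 0.23, each with an adjusted p of 0.0292. Second probe sets of Clu and Plin2, each at 0.01, and 2 further ones of Cp did not pass. Gnpnat1, an enzyme of amino sugar synthesis, fell by 0.23 (adjusted p = 0.0483). Havcr1 had a value of 0.73 and did not pass (adjusted p = 0.683).

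Limma called 10 probe sets in females, 9 higher and 1 lower in affected rats, and 1393 had an unadjusted p under 0.05. All 3 values of one group lay above all 3 of the other in each call, as in 14.7% of all probe sets, where chance gives 10%. Each of the 7 named calls ended in some of the 12 fits that left out 1 array. Spp1 ended without wild type male replicate 1, each wild type female or affected female replicate 3 (adjusted p up to 0.112). The calls of Clu, Cp, Fcer1g and Vkorc1 ended in 9 such fits each, that of Plin2 in 10 and that of Gnpnat1 in 12, each with every wild type female and affected female replicate 3 among them, and with adjusted p up to 0.138, 0.154, 0.154, 0.132, 0.132 and 0.154. The count was 0 without wild type male replicate 1, wild type female replicate 3 or affected female replicate 3, and 18 without affected male replicate 3.

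Camera called 13 gene lists in females at the preset correlation and fry called 0, with adjusted p from 0.115 to 0.565 for these lists. In the injury list 3 of 28 genes rose, 11 when adjusted over the list alone, with a median of 0.28 and a camera adjusted p of 7.16e-14 (adjusted p = 0.357 with an estimated correlation). Among matrix genes 0 of 44 passed the test and 6 rose when adjusted over the list alone, at a median of 0.16 (camera adjusted p = 2.35e-11; adjusted p = 0.392 with an estimated correlation). Mgp and Dcn had values of 0.83 and 0.66 with adjusted p of 0.101 and 0.21. Of the leukocyte genes 1 rose, 4 when adjusted over the list alone, at a median of 0.13 (camera adjusted p = 7.9e-10; adjusted p = 0.357 with an estimated correlation). In the list of antigen presentation 0 passed and 8 rose when adjusted over the list alone, at a median of 0.08 (camera adjusted p = 1.34e-07; adjusted p = 0.357 with an estimated correlation). Cd74, the invariant chain of class II molecules, had a value of 0.44 with an adjusted p of 0.065. The complement list had 0 called members by either adjustment and a median of 0.09 (camera adjusted p = 0.0011; adjusted p = 0.357 with an estimated correlation). The cell cycle list had 0 called members, 2 when adjusted over the list alone, and a median of 0.04 (camera adjusted p = 0.000269; adjusted p = 0.47 with an estimated correlation).

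The other list calls in females each ended in some fit that left out a single array. The chemokine list had 0 called members and a median of 0.03 (camera adjusted p = 0.0225; adjusted p = 0.392 with an estimated correlation), and its call ended without wild type female replicate 1 (0.0985) or affected female replicate 2 (0.137). The proximal tubule list, at -0.04 with 0 called members (camera adjusted p = 0.0225; adjusted p = 0.651 with an estimated correlation), ended without wild type female replicate 1 (0.0923) or affected female replicate 2 (0.137) or 3 (0.282). The list of the thick ascending limb and distal convoluted tubule, at -0.06 (camera adjusted p = 0.0141; adjusted p = 0.392 with an estimated correlation), ended without wild type female replicate 3 (0.0547) or affected female replicate 2 (0.137). Endothelial genes, at -0.03 (camera adjusted p = 0.0277; adjusted p = 0.392 with an estimated correlation), lost the call with the mean over probe sets (0.0539) and without wild type female replicate 2 (0.0739) or 3 (0.13) or affected female replicate 2 (0.25). The 5 genes of the blood cell list, of which 2 fell when adjusted over the list alone, had a median of -0.21 (camera adjusted p = 0.0125; adjusted p = 0.357 with an estimated correlation), and without affected female replicate 3 the adjusted p was 0.0683. This list is called the haemoglobin list below but also holds Slc4a1, which is not a haemoglobin gene. The probe sets of Slc4a1 stood at -0.498 and -0.675 in females and did not pass over all probe sets. The glycolysis list, at 0.03 (camera adjusted p = 0.0269; adjusted p = 0.481 with an estimated correlation), ended with quantile normalization (0.288), without the dimmest 40% of probe sets (0.0906) and without wild type female replicate 1 (0.238) or affected female replicate 3 (0.282). The cholesterol synthesis list, at 0.04 (camera adjusted p = 0.0349; adjusted p = 0.593 with an estimated correlation), ended without the dimmest 40% (0.147), wild type female replicate 1 (0.231) or 2 (0.0739) or affected female replicate 3 (0.321).

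**Figure D2:**
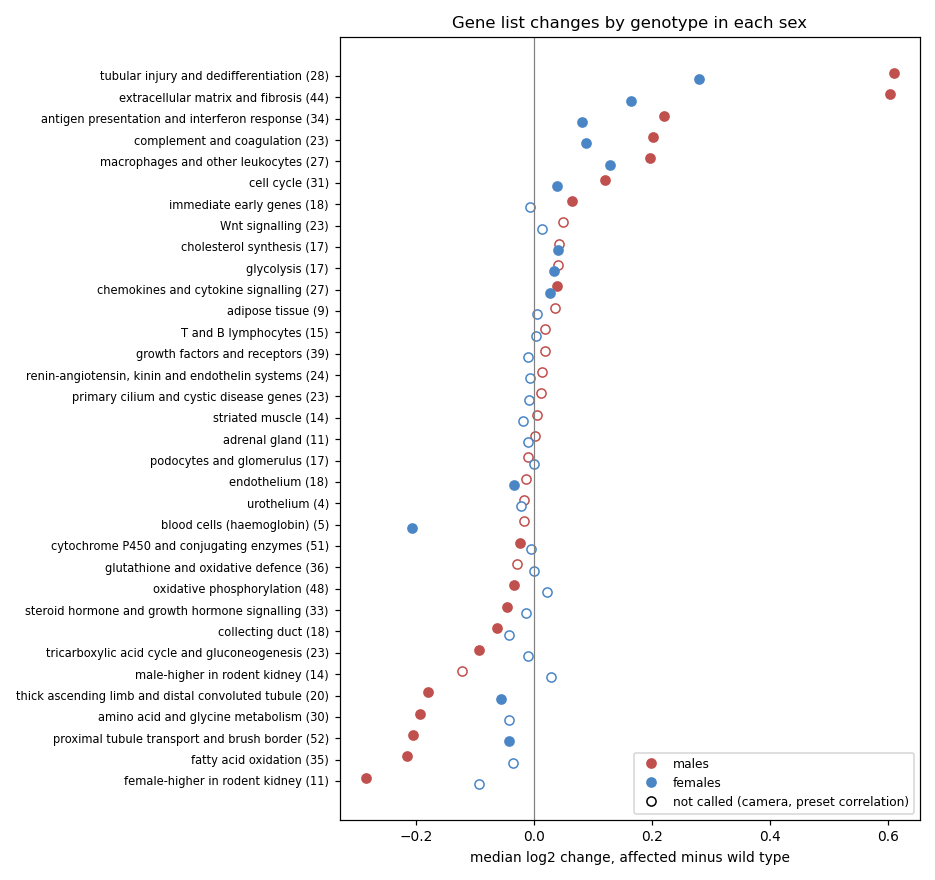
Median log2 change, affected minus wild type, of 34 gene lists with the number of measured genes in parentheses, in males (red) and females (blue). Filled points were called by camera at the preset correlation and open points were not, and the matrix list stood at 0.60 in males and 0.16 in females.

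The effect of genotype was then compared between the sexes. The interaction tests whether affected and wild type rats differ by another amount in males than in females, and limma called 0 of 15866 probe sets for it. The smallest adjusted p was 0.452, 992 probe sets had an unadjusted p under 0.05, and 791 of these changed in the more positive direction in males. With the block within genotype limma's smallest adjusted p was 0.0881 and 1643 had an unadjusted p under 0.05, again with 0 called. Of the 5 named genes of smallest p, Adh1c changed by -0.87 in males and 0.04 in females, an interaction of -0.90 (SE 0.13, adjusted p = 0.452). Myo6, an actin motor of the brush border, had -0.53 in males and 0.11 in females (adjusted p = 0.452), but its second probe set had -0.25 in males and -0.27 in females. The collagen genes Col5a2 and Col4a2 had interactions of 0.60 and 0.53 and Nudt21, a factor of RNA 3' end processing, 0.23, each with an adjusted p of 0.528. All other settings run and all 12 fits with 1 array left out also gave 0.

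Of the 878 probe sets called in males 815 (92.8%) changed in the same direction in females, beside 64% of all 15866 probe sets. All 9 called higher in females were also called higher in males, where independent lists of these sizes would share 0.427. The median absolute change of the 878 was 0.318 in males and 0.128 in females, and 864 changed more in males, the sex in which they were chosen. Among the 1047 probe sets called for the genotype effect averaged over the sexes, 904 (86.3%) changed more in males, with medians of 0.282 and 0.151. Over all 15866 probe sets the share was 60.9%. The average weighs the sexes equally, but the spread within groups was largest in affected males. The choice may therefore favour probe sets with large male deviations. With 1 array left out, the share among probe sets called for the averaged effect lay between 78.4% and 91.7%. Camera called 18 lists for the interaction, with medians of 0.35 for matrix, 0.29 for injury and -0.14 for proximal tubule genes. All 44 matrix genes had a more positive change in males (camera adjusted p = 1.84e-16; adjusted p = 0.19 with an estimated correlation). For the injury list it was 5.68e-08 and adjusted p = 0.236 with an estimated correlation, and for the proximal tubule list 1.13e-08 and adjusted p = 0.236 with an estimated correlation. Adjusted over the list alone, 8 matrix genes and 6 injury genes passed, and fry called 0 lists.

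**Figure D3:**
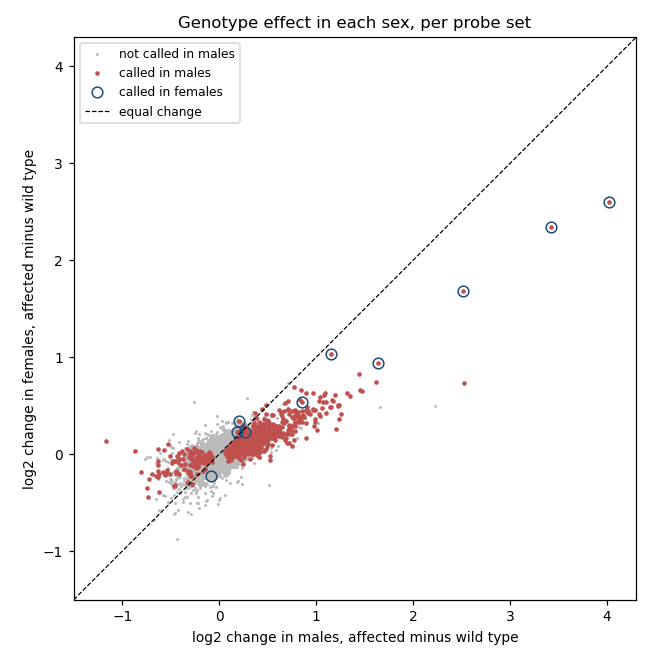
Log2 change of each probe set, affected minus wild type, in males (x axis) and females (y axis), with probe sets called in males in red, those called in females ringed in blue and equal change dashed. Of the 878 red points 864 changed more in males, the sex in which they were chosen.

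Across both sexes, affected rats differed on average from wild type rats in 1047 probe sets, 856 higher and 191 lower. Quantile normalization gave 599 higher and 389 lower. In the injury list 18 of 28 genes rose, 22 when adjusted over the list alone, with a median of 0.42 (camera adjusted p = 2.38e-16), and in the matrix list 29 of 44 rose, 39 when adjusted over the list alone with 1 that fell, with a median of 0.41 (camera adjusted p = 4.86e-21). Both lists had adjusted p = 0.115 with an estimated correlation. In the proximal tubule list 8 of 52 fell and 1 rose, 14 and 2 when adjusted over the list alone, with a median of -0.13 (camera adjusted p = 3.91e-08; adjusted p = 0.218 with an estimated correlation; fry 0.06). With each same-numbered pair of a male and a female of a genotype averaged to 1 value, 3 pairs against 3, limma called 179 probe sets, 170 of them among the 1047. The count was 546 without wild type male replicate 2, 656 and 640 without wild type female replicates 2 and 3, and 639 without affected female replicate 3.

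Single genes for transporters, enzymes and receptors differed between the sexes of wild type rats. As lists, proximal tubule transport (camera adjusted p = 0.0763), cytochrome P450 and conjugating enzymes (0.0534) and steroid and growth hormone signalling (0.333) did not pass. Among genes higher in males, Rgn, encoding the calcium-binding regucalcin, was at least 9.65-fold higher (SE 0.25, adjusted p = 0.000127), with females at the floor of the scale, and Akr1c13, an aldo-keto reductase, 9.2-fold (SE 0.10, adjusted p = 2.3e-07). Slco1a1 was at least 9-fold higher (adjusted p = 8.78e-05), at 9.10 ± 0.32 in males and 5.93 ± 0.26 in females (SD, n = 3), the latter at the floor, and Slc22a2, an organic cation transporter of the proximal tubule, 6.55-fold (adjusted p = 3.69e-06). Prlr, the prolactin receptor, was 3.3-fold higher in males (adjusted p = 0.00011), Inmt, an indolethylamine methyltransferase, 2.75-fold (adjusted p = 1.39e-05), and Cyp4a8, a fatty acid hydroxylase, 2.47-fold (adjusted p = 0.000133). Tff3, a trefoil peptide of epithelial surfaces, and Slco1a3, an organic anion transporter, were each 2.5-fold higher (adjusted p = 0.00314 and 0.00871). Gamt, which completes creatine synthesis, and Hsd11b1, which regenerates active glucocorticoid, were 2.01-fold and 2.06-fold higher (adjusted p = 0.000118 and 8.4e-05), and Sult1b1, a sulfotransferase, was higher by 1.28 (adjusted p = 0.00471).

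Among genes higher in wild type females, Xist led with a change of -3.58 (adjusted p = 1.15e-07). Slc22a7, an organic anion transporter, stood at -2.54 (SE 0.17, adjusted p = 5.27e-05) and Cpe, a prohormone-processing carboxypeptidase, at -2.28 (SE 0.15, adjusted p = 3.74e-05). Akr1b7, an aldose reductase-like enzyme, stood at -2.58 (adjusted p = 0.00335), with males at the floor of the scale. Adh1c stood at -1.66 (adjusted p = 1.77e-05), Pld1, a phospholipase D, at -1.73 (adjusted p = 7.63e-05), and Sod3, the extracellular superoxide dismutase, at -1.63 (adjusted p = 2.59e-05). Of 5 Pld1 probe sets 3 passed. Slc5a6, a vitamin transporter, stood at -1.47 (adjusted p = 3.24e-06) and Cubn, the endocytic receptor cubilin, at -0.91 (adjusted p = 2.59e-05). Vwf, the von Willebrand factor of endothelium, stood at -1.26 (adjusted p = 0.000737), with males near the floor of the scale. Fdft1, the squalene synthase of cholesterol synthesis, stood at -1.11 (adjusted p = 7.63e-05), Fah, an enzyme of tyrosine breakdown, at -0.55 (adjusted p = 0.000133), and the growth factor gene Fgf9 at -0.61 (adjusted p = 0.001).

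**Figure D4:**
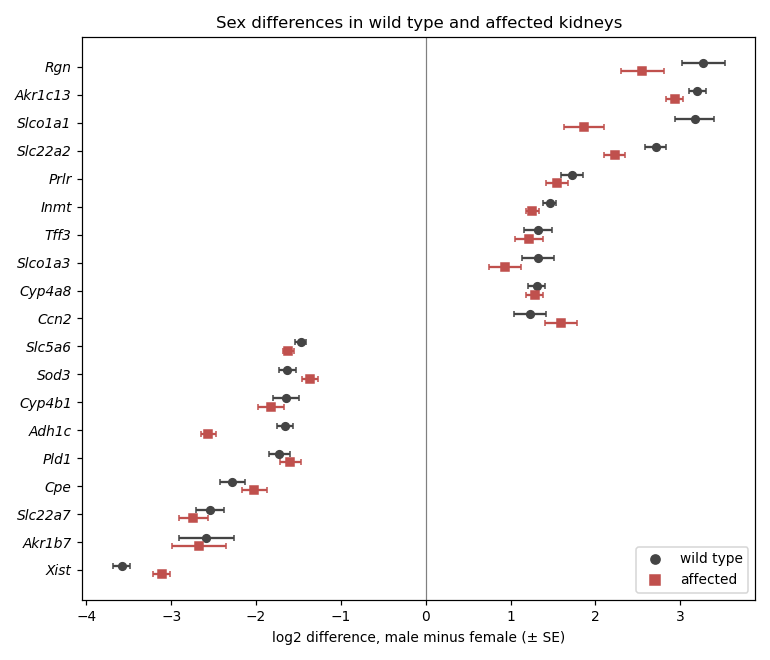
Log2 difference, male minus female, ± SE for 19 genes in wild type (dark circles) and affected rats (red squares), n = 3 per group. Rgn stood at 3.27 and 2.55, and Xist at -3.58 and -3.11.

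Limma called 207 probe sets between the sexes of wild type rats, 95 higher and 112 lower in males, from 75 and 85 genes. In each call all 3 values of one sex lay above all 3 of the other, as in 17% of all probe sets against 10% by chance. In the list known as higher in male rodent kidney 3 of 14 genes were higher in males and 1 was lower, also when adjusted over the list alone, at a median of 0.04 (camera adjusted p = 0.00736; adjusted p = 0.27 with an estimated correlation). The lower one was Cyp4b1, a cytochrome P450 of fatty acids and foreign compounds, at -1.65 (adjusted p = 0.000526). In the list known as higher in females 2 of 11 were lower in males and 2, Prlr and Hsd11b1, were higher (3 higher and 4 lower when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.953). The cell cycle list had all 31 genes on the male side at a median of 0.05, with 0 called by either adjustment (camera adjusted p = 9.04e-07; adjusted p = 0.516 with an estimated correlation; fry 0.266). Endothelial genes were lower in males at a median of -0.06, with Vwf called of 18 by either adjustment (camera adjusted p = 0.00233; adjusted p = 0.355 with an estimated correlation).

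Further lists stood at higher camera adjusted p between the sexes of wild type rats than the called lists above. Genes of podocytes and the glomerulus had a median of -0.07, with 0 called and 2 lower when adjusted over the list alone (camera adjusted p = 0.00891; adjusted p = 0.273 with an estimated correlation), and without the dimmest 40% of probe sets the adjusted p was 0.0895. Collecting duct genes had a median of -0.12 with 0 called, 1 when adjusted over the list alone (camera adjusted p = 0.0414; adjusted p = 0.493 with an estimated correlation). That call ended with fry (0.169) and without wild type male replicate 3 (0.122), wild type female replicate 2 (0.345) or affected female replicate 2 (0.051). The list of oxidative phosphorylation, at 0.04 with 0 called (camera adjusted p = 0.0414; adjusted p = 0.952 with an estimated correlation), ended with fry (0.866), quantile normalization (0.138) and without wild type male replicate 2 (0.247) or 3 (0.186) or wild type female replicate 1 (0.0826) or 2 (0.116). Fatty acid oxidation and glutathione lists, each at an adjusted p of 0.0505, passed with the block within genotype (0.0321 and 0.03). The count of probe sets was 129, 119 and 127 without wild type male replicates 1, 2 and 3, and 136 and 129 without wild type female replicates 2 and 3.

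Single genes for transporters and enzymes also differed between the sexes of affected rats, although the list of cytochrome P450 and conjugating enzymes did not pass (camera adjusted p = 0.802). Akr1c13 was 7.65-fold higher in males (adjusted p = 5.28e-07), Slc22a2 4.68-fold (adjusted p = 1.41e-05), and, with females at or near the floor, Rgn at least 5.86-fold (adjusted p = 0.000786) and Slco1a1 at least 3.64-fold (adjusted p = 0.00319). Ccn2, encoding connective tissue growth factor, was 3.02-fold higher in affected males than in affected females (SE 0.19, adjusted p = 0.00267). It was also 2.34-fold higher in males in wild type (adjusted p = 0.013), a call that ended without wild type male replicate 1 or 3 or wild type female replicate 2 or 3, with adjusted p up to 0.0671. On the female side Xist stood at -3.11 (adjusted p = 4.48e-07), Slc22a7 at -2.74 (adjusted p = 3.51e-05), Adh1c at -2.56 (adjusted p = 7.22e-07), Cpe at -2.02 (adjusted p = 0.000107), Slc5a6 at -1.62 (adjusted p = 1.28e-06) and Cubn at -1.10 (adjusted p = 6.97e-06). Acot1, an acyl-CoA thioesterase, stood at -1.08 (adjusted p = 0.000469) and Fah at -0.82 (adjusted p = 1.24e-05). Col5a2, a fibrillar collagen gene, was higher in males by 0.57 (adjusted p = 0.00262), Fcer1g by 0.48 (adjusted p = 0.00623) and Myc by 0.19 (adjusted p = 0.0112). Slc22a24 stood at -0.76 (adjusted p = 0.00248).

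In affected rats the matrix list had 10 of 44 genes higher in males and 0 lower, 25 higher when adjusted over the list alone, with a median of 0.35 (camera adjusted p = 1.77e-14; adjusted p = 0.333 with an estimated correlation). The injury list had 2 of 28 higher, 17 when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 1.13e-08; adjusted p = 0.333 with an estimated correlation). Of the cell cycle genes 6 of 31 were higher, 19 when adjusted over the list alone, with a median of 0.14 (camera adjusted p = 4.26e-10; adjusted p = 0.333 with an estimated correlation). In the leukocyte list 3 of 27 were higher, 11 when adjusted over the list alone, with a median of 0.12 (camera adjusted p = 4.15e-06; adjusted p = 0.333 with an estimated correlation). The thick ascending limb and distal convoluted tubule list was lower in males at a median of -0.16, with 1 of 20 called, or 4 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.000342; adjusted p = 0.333 with an estimated correlation; fry 0.0764). The called gene, Egf, lost its call with the block within genotype. Collecting duct genes were lower at a median of -0.11, with 1 of 18 called and 3 when adjusted over the list alone (camera adjusted p = 4.04e-05; adjusted p = 0.207 with an estimated correlation).

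The remaining list calls between affected males and females ended under at least 1 alternative. The complement list, with 3 of 23 genes higher (camera adjusted p = 0.0043; adjusted p = 0.333 with an estimated correlation), ended without affected female replicate 2 (0.0641). The chemokine list (camera adjusted p = 0.0115; adjusted p = 0.333 with an estimated correlation) ended without affected male replicate 3 (0.0719). The antigen presentation list, with 2 higher (camera adjusted p = 0.0413; adjusted p = 0.587 with an estimated correlation), ended with fry (0.0908), the mean over probe sets (0.0558) and without affected male replicate 1 (0.0842) or 3 (0.476) or affected female replicate 1 (0.0975) or 2 (0.211). Its 2 called genes, Ifi27 and Psmb10, lost their calls with the block within genotype. Immediate early genes (camera adjusted p = 0.0399; adjusted p = 0.389 with an estimated correlation) ended without the dimmest 40% of probe sets (0.155), affected male replicate 2 (0.154) or 3 (0.0719) or affected female replicate 1 (0.188) or 2 (0.097). Proximal tubule genes, 3 higher and 5 lower in males at a median of -0.03 (camera adjusted p = 0.00999; adjusted p = 0.676 with an estimated correlation), ended with fry (0.532), quantile normalization (0.185) and without affected male replicate 3 (0.883, at a median of 0.0232) or affected female replicate 1 (0.171). The list of fatty acid oxidation, 2 higher and 3 lower at -0.07 (camera adjusted p = 0.00134; adjusted p = 0.573 with an estimated correlation), ended with fry (0.349) and without affected male replicate 3 (0.0662, at a median of 0.00895) or affected female replicate 1 (0.199). Amino acid genes, 1 higher and 4 lower at -0.07 (camera adjusted p = 0.000546; adjusted p = 0.461 with an estimated correlation), ended with fry (0.17) and without affected male replicate 3 (0.0662). Oxidative phosphorylation, at -0.04 (camera adjusted p = 0.0043; adjusted p = 0.579 with an estimated correlation), ended with fry (0.543) and without affected male replicate 2 (0.178) or affected female replicate 1 (0.321). The tricarboxylic acid list, at -0.03 (camera adjusted p = 0.0399; adjusted p = 0.676 with an estimated correlation), ended with fry (0.635), quantile normalization (0.185) and without the dimmest 40% (0.095), affected male replicate 2 (0.131) or 3 (0.757) or affected female replicate 1 (0.744), the last 2 at medians of 0.00716 and 0.0122. Podocyte genes, at -0.05 (camera adjusted p = 0.0399; adjusted p = 0.333 with an estimated correlation), ended with fry (0.223), the mean over probe sets (0.0787), quantile normalization (0.116) and without the dimmest 40% (0.228), affected male replicate 2 (0.125) or 3 (0.0662) or affected female replicate 1 (0.0544) or 2 (0.172). The list known as higher in females, at -0.08 with 2 higher and 3 lower in males (camera adjusted p = 0.0419; adjusted p = 0.333 with an estimated correlation), ended with fry (0.119), quantile normalization (0.338), the block within genotype (0.106) and without the dimmest 40% (0.128), wild type female replicate 1 (0.0514) or 2 (0.0648), affected male replicate 2 (0.126) or 3 (0.208) or affected female replicate 1 (0.163) or 2 (0.101).

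Limma called 375 probe sets between affected males and females, 194 higher and 181 lower in males, from 162 and 145 genes. Quantile normalization gave 160 higher and 229 lower, and centring the arrays on their medians 143 and 204, so the direction of the excess depended on the scaling. In each of the 375 calls the groups did not overlap, as in 16.7% of all probe sets against 10% by chance. The count was 242 without wild type male replicate 2, 231 without affected male replicate 3, and 193 and 216 without affected female replicates 1 and 3. Calls shared between wild type and affected rats numbered 60 higher and 88 lower in males, where independent lists would share 1.16 and 1.28. Averaged over the genotypes, 563 probe sets differed between the sexes, 253 higher and 310 lower in males, and 370 without wild type male replicate 3.

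Lists for tissues that could be dissected along with the kidney gave no call between affected and wild type males. The camera adjusted p was 0.417 for the blood cell list, 0.871 for adipose tissue, 0.435 for adrenal gland, 0.651 for striated muscle and 0.417 for urothelium. Lymphocytes of the T and B lineages (0.582), podocytes (0.871) and endothelium (0.71) gave no call either. Glycolysis (0.36), cholesterol synthesis (0.07), glutathione and oxidative defence (0.134), the renin-angiotensin, kinin and endothelin systems (0.71), growth factors and receptors (0.871) and Wnt signalling (0.242) did not pass. The list of the primary cilium and cystic disease genes, which holds known genes of cyst formation, did not pass in males (0.756), and 1 of its 23 genes, Bbs2, a component of the ciliary transport complex, fell by 0.43 (adjusted p = 0.0285). The call of Bbs2 ended without wild type male replicate 2 or 3 or affected male replicate 2 or 3, with adjusted p up to 0.11.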

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

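Of the tests in this part, those of a larger spread among the female arrays, of a lower share of proximal tubule RNA and of retained blood were chosen only after the result was seen, as were the 3'/5' covariate, the splits that respect the pairs of males and females and the intervals beside the sex-dependent genes. Groups of 3 arrays were too small to test single arrays as outliers.

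Differences between the genotype effects of males and females were tested for each gene list, and camera at its preset correlation called the following, given as the median of the male minus the female effect. The positive ones were 0.286 for tubular injury and dedifferentiation, 0.347 for extracellular matrix, 0.141 for leukocytes, 0.0965 for antigen presentation, 0.133 for complement, 0.0716 for cell cycle and 0.0745 for immediate early genes. On the negative side stood -0.138 for proximal tubule, -0.0534 for thick ascending limb and distal convoluted tubule, -0.00586 for collecting duct, -0.13 for fatty acid oxidation, -0.0425 for oxidative phosphorylation and -0.0566 for the tricarboxylic acid cycle. The values were -0.149 for amino acid metabolism, -0.00423 for cytochrome P450 and conjugating enzymes, -0.0967 for genes known as higher in male kidney, -0.167 for those known as higher in female kidney and -0.0254 for steroid and growth hormone signalling. With an estimated correlation 0 of these 18 stayed called, with adjusted p from 0.19 to 0.481, and fry called 0. Of the 18 calls 6 ended with single arrays left out. Collecting duct ended without wild type male replicate 1 (0.0926) or 2 (0.0736), wild type female replicate 1 (0.328) or 3 (0.0761), affected male replicate 2 (0.117) or 3 (0.097) or affected female replicate 2 (0.0703) or 3 (0.0789), and the median turned to 0.0365 and 0.00244 without those wild type females. It also ended with quantile normalization (0.124), the 3'/5' covariate (0.0522) and the block within genotype (0.0503). The thick ascending limb and distal convoluted tubule list ended with quantile normalization (0.124) and without wild type male replicate 1 (0.0664) or 2 (0.0736), wild type female replicate 2 (0.062), affected male replicate 2 (0.104) or 3 (0.293) or affected female replicate 1 (0.0517) or 3 (0.119). Steroid and growth hormone signalling ended with quantile normalization (0.125), the covariate (0.069) and without the dimmest 40% of probe sets (0.154), wild type male replicate 1 (0.0926) or 2 (0.0701), wild type female replicate 1 (0.108) or 3 (0.0524), affected male replicate 2 (0.0524) or 3 (0.106) or affected female replicate 1 (0.203) or 2 (0.0689). Cell cycle ended without wild type female replicate 3 (0.131), affected male replicate 3 (0.152) or affected female replicate 1 (0.0615), and the tricarboxylic acid cycle without affected male replicate 3 (0.096) or affected female replicate 1 (0.168). Immediate early genes ended without the dimmest 40% (0.108) or affected male replicate 2 (0.0557). Outside the genes tested, the middle control probe set of GAPDH was 0.175 higher in affected than in wild type males (SE 0.0341, adjusted p = 0.0356 over the 57 controls), with 0.12 in females (adjusted p = 0.38).

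The first pattern was the 878 genotype calls in males beside 10 in females. Leaving out affected male replicate 3, which lay apart on the first component, left 500, which argues against one severe male as the whole cause. The 3'/5' covariate gave 1054 in males and 20 in females, so RNA quality as this 1 measure captures it does not account for the difference. Its group means lay close together, from 0.885 to 0.981, and other aspects of RNA quality were not tested. A larger spread among female arrays cannot lower the female count through the test, because the 4 groups share 1 estimate of the spread. The root mean SD within groups was also largest in affected males, at 0.102, with 0.0644 in wild type males and 0.0784 and 0.0889 in wild type and affected females. The changes would then be of like size. But with any 1 array left out, at least 78.4% of probe sets called for the mean genotype effect changed more in males. Over all 15866 probe sets, with every array in, 60.9% did. The larger spread of affected males may add to these shares. What stays open is whether disease had advanced further in males at this age or males respond more. Since the gene by gene interaction called 0, a larger effect in males is a hypothesis that these data do not show for single genes. For groups of genes they may support it, but only by camera at the preset correlation, since an estimated correlation and fry left 0 lists called.

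The second pattern was higher matrix, injury and leukocyte genes with lower proximal tubule genes in affected males. A lower share of RNA from the proximal tubule alone would raise other nephron segments and leukocytes alike, but the mean of the thick ascending limb and distal convoluted tubule list changed by -0.164 while that of the leukocyte list changed by 0.336. A lower share of RNA from all tubule segments would lower both tubule lists. It was not tested and stays open. The leukocyte score minus the limb score lay between -2.4 and -2.33 in wild type and between -2.06 and -1.68 in affected males. Retained blood would raise the haemoglobin list, whose mean changed by -0.167, with 7.47 to 7.64 in wild type and 7.3 to 7.46 in affected males. Most of that fall came from 1 member, Slc4a1, at -0.669, which is not a haemoglobin gene. The haemoglobin gene Hbb lay between 10.959 and 11.145 in wild type and between 10.572 and 11.006 in affected males, which overlap. The values thus show no rise of blood genes, but the fall of the list is not a measure of less blood. Infiltration, altered tubule cells and expansion of matrix-producing cells stay open as untested biological explanations.

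The third pattern concerned genes that differ between the sexes, chosen in each of 3 rotations by a difference over 1 between 1 wild type male array and the mean of the wild type females, with Xist set aside, and then measured as affected males against the wild type males not used for the choice. Loss of male-type expression was written beforehand as a fall of male-higher genes together with a rise of female-higher genes by over 0.1 in affected males. The female-higher medians were -0.0272, -0.0456 and -0.0837, with 95% intervals up to 0.026, 0.0057 and 0.0124. These values argue against a shift towards female-type expression. A loss that lowers male-higher genes alone needs no such rise and is not excluded by them. Male-higher genes had medians of -0.231, -0.243 and -0.285, with 95% intervals under 0. In affected females, with 1 wild type female array used for the choice instead, their medians were -0.0148, -0.0205 and -0.0257, with intervals that include 0. All these intervals treat probe sets as independent and cover the spread between probe sets, not between rats. The 3 rotations share the same affected rats. The floor of the scale limits these values too. Some male-higher genes, such as Rgn and Slco1a1, lie at the floor in females and can hardly fall there. The female medians near 0 thus do not show that females keep these genes. Some female-higher genes, such as Akr1b7 and Vwf, lie at or near the floor in males, which limits their fall. A general fall of tubule transcripts predicts a fall in both groups, with -0.231 as the smallest fall of male-higher genes, but the intervals of female-higher genes include 0, so that it cannot be told apart from a fall limited to male-higher genes. The list known as higher in female kidney, at a median of -0.285 in affected males (camera adjusted p = 6.26e-05; adjusted p = 0.0909 with an estimated correlation), speaks against such a limited fall, and the list known as higher in males did not pass (0.0603), but of the 2 called members of the female list Prlr was higher in males in these rats and Slc22a24 did not pass between the sexes of wild type rats.

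Other splits of the samples tell how often chance gives as many calls. For the comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real counts were 878, 10, 207 and 375 for genotype in males, genotype in females, sex in wild type and sex in affected rats, and the highest of the other splits gave 1, 0, 0 and 11, so that 1 of 10 splits, the real one, reached each. If the numbers pair males and females within a genotype, splits of the wild type and affected rats for the averaged genotype effect have to keep 6 pairs together, which leaves 10, too few for a share under 0.05. There 1, the real one, reached the 1047 calls, with 2 as the highest of the others, and among 100 splits drawn without regard to the pairs the highest other gave 87. For sex averaged over the genotypes, 1 of the 32 splits that exchange the sexes within pairs, the real one, reached the 563 calls, with 1 as the highest of the others. That is a share of 0.0312, under 0.05 and the lowest these splits can give, and it rests on the pairing inferred from the data. The other splits carry the real sex effect in their spread, which lowers their counts. Chance is unlikely there but not excluded. Of the 10 splits for sex in wild type and sex in affected rats, 4 part all 3 pairs as the real one does, with 0 and 1 as the highest of the others, and the 6 that part 1 pair gave at most 0 and 11. For the interaction the real count was 0, which any split reaches, as 100 of 100 did, so the splits say nothing on it. The highest gave 315, which points to the structure of the samples, since those splits mix the effects of sex and genotype into it.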

How the results depend on the processing

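Of the alternatives in this part, the block within genotype, the means of pairs and the 3'/5' covariate were chosen only after the result was seen. No named gene that was called turned its direction in the alternatives run, and no called list turned camera's direction. The medians of 4 called lists turned sign in fits with 1 array left out in which the call also ended: proximal tubule, fatty acid oxidation and the tricarboxylic acid cycle for sex in affected rats, and collecting duct for the interaction. The count for the interaction was 0 in each alternative run for it. Counts within 1.5 times that of the report are mostly not listed singly. For the others below the cause was not tested, except where the alternative itself is stricter or uses fewer arrays.

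A test against a 1.2-fold change is stricter by construction. It left 32 calls for genotype in males, 0 for genotype in females, 51 for sex in wild type and 56 for sex in affected rats, with 14 for genotype and 85 for sex averaged over the other factor. Fits on the 6 arrays of a comparison alone gave 190 for genotype in males, 1 for genotype in females and 106 for sex in affected rats. For sex in wild type they gave 197, near the 207 of the report. These fits have fewer arrays to estimate the spread, but so does the one for sex in wild type. The number of arrays is thus not the whole cause. The root mean SD within groups was 0.102 and 0.0889 in affected males and females, with 0.0644 and 0.0784 in wild type. The floor at the 20th percentile gave 0 for genotype in females and 226 for sex in affected rats, and the cause was not tested. Array weights gave 31 for genotype in females and 506 for sex in wild type, beside 295 for sex in affected rats, and the cause was not tested. The report had 207 calls for sex in wild type and 375 in affected rats. Which genotype showed more sex calls therefore depended on the fit, and it turned with array weights and with a comparison's own arrays. For genotype in females, quantile normalization gave 5, leaving out the dimmest 40% of probe sets 18 and the 3'/5' covariate 20, and the cause was not tested.

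With 1 array left out, and so with fewer arrays, the counts lay between 307 and 1061 for genotype in males, 0 and 18 for genotype in females, 119 and 225 for sex in wild type and 193 and 517 for sex in affected rats. They lay between 546 and 1168 for genotype and 370 and 640 for sex averaged over the other factor. For genotype in females the count was 0, 2 and 1 without wild type male replicates 1, 2 and 3, and 2, 1 and 0 without wild type female replicates 1, 2 and 3. It was 5 and 18 without affected male replicates 1 and 3, and 3 and 0 without affected female replicates 1 and 3. Of the named calls 29 of 74 for genotype in males, 0 of 7 for genotype in females, 34 of 42 for sex in wild type and 40 of 61 for sex in affected rats passed in all 12 such fits.

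Gene lists depended most on the correlation between genes. With an estimated correlation 0 lists were called in each of the 7 comparisons, where the preset had called 18, 13, 6 and 17 for the comparisons of 2 groups, 18 for the interaction, and 16 and 9 for the averaged effects. The estimate allows for genes that vary together within groups, which widens the test. Fry called 0 lists for genotype in females, 11 for sex in affected rats and 0 for the interaction, and the cause was not tested. With 1 array left out, the lists called numbered 16 to 21 for genotype in males, 9 to 15 for genotype in females, 4 to 11 for sex in wild type and 8 to 17 for sex in affected rats, then 14 to 19 for the interaction, 14 to 18 for genotype averaged and 8 to 11 for sex averaged. Sex in wild type had 10 without wild type female replicate 1 and 11 without affected male replicate 1. Sex in affected rats had 8 without affected male replicate 3 and 9 without affected female replicate 1.

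Among 331 values of named genes, 308 kept direction and side of the threshold with quantile normalization, 316 with centred arrays, 313 with a variance trend, 306 with array weights, 273 with the floor and 317 with the 3'/5' covariate. Without the dimmest 40% it was 272 of 278, and with each comparison's own arrays 236 of 326. Of 238 list values, 207 kept both with quantile normalization, 225 with the mean over probe sets and 229 with the covariate, and 163 of 203 without the dimmest 40%.

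The replicate number as a block over all groups gave 1114 calls for genotype in males and 10 in females. The numbers were not treated as pairing the genotypes, because not every same-numbered pair passed the limit of 0.1, but a partial pairing is not excluded. Same-numbered wild type and affected rats correlated at -0.114 to 0.343 in males and 0.00642 to 0.368 in females. The block within genotype gave 185 calls for sex in wild type, 530 in affected rats and 723 for sex averaged. For the interaction it gave 0, with 0.0881 as the smallest adjusted p and 1643 unadjusted p under 0.05. For genotype averaged over the sexes, the means of the pairs, with fewer values to estimate the spread, gave 179 calls, and the list of immediate early genes ended (0.064). The block within genotype ended the calls of Gsto1 (0.0745), Haao (0.0977), Hao2 (0.0907) and Slc7a12 (0.0629) in wild type, and of Egf (0.0794), Eno1 (0.0807), Ifi27 (0.0621), Kynu (0.109), Psmb10 (0.0692) and Stmn1 (0.105) in affected rats. Col4a4 passed with this block in wild type (0.0393), and Idh3a (0.0231), Col4a4 (0.028), Icam1 (0.0378) and Slc4a1 (0.0338) in affected rats. Apart from these, the 3 lists given above with their values and the collecting duct list for the interaction (0.0503), the pairing changed no call of a named gene or list in the comparisons of the sexes and the interaction, nor of another list for the averaged genotype effect.

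Signal over background limited weakly expressed genes. With 34% of values under 6 and a floor at 5.827, a change that ends in the floor is smaller on this scale than in the kidney.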

Other observations

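The genes and lists in this part follow from rules and tests set before the data were examined, and no test here was chosen only after the result was seen. Averaged over the sexes, 15 of 27 leukocyte genes rose in affected rats, 19 when adjusted over the list alone, at a median of 0.17 (camera adjusted p = 7.71e-12; adjusted p = 0.115 with an estimated correlation). Antigen presentation had 17 of 34 that rose, 19 when adjusted over the list alone, at 0.12 (camera adjusted p = 2.44e-09; adjusted p = 0.115 with an estimated correlation). Complement had 10 of 23, 14 when adjusted over the list alone, at 0.14 (camera adjusted p = 5.69e-06; adjusted p = 0.115 with an estimated correlation). In the list of fatty acid oxidation 6 of 35 fell, 9 when adjusted over the list alone, at -0.13 (camera adjusted p = 2.83e-07; adjusted p = 0.218 with an estimated correlation; fry 0.0529), and for amino acid metabolism 3 of 30, 6 when adjusted over the list alone, at -0.11 (camera adjusted p = 2.8e-07; adjusted p = 0.209 with an estimated correlation). Cholesterol synthesis had 1 of 17 that rose, 3 when adjusted over the list alone (camera adjusted p = 0.0289; adjusted p = 0.516 with an estimated correlation). That call ended with fry (0.0615) and without the dimmest 40% of probe sets (0.123), wild type female replicate 1 (0.0942), affected male replicate 3 (0.0967) or affected female replicate 3 (0.0945).

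Averaged over the genotypes, 9 of 31 cell cycle genes were higher in males, 21 when adjusted over the list alone, at a median of 0.10 (camera adjusted p = 3.64e-11; adjusted p = 0.372 with an estimated correlation). Collecting duct genes were lower in males at -0.13, with 1 of 18 called and 5 when adjusted over the list alone (camera adjusted p = 0.000106; adjusted p = 0.234 with an estimated correlation). Single genes outside these lists differed between the sexes in both genotypes. Agt, encoding angiotensinogen, was higher in males by 0.27 in wild type (adjusted p = 0.00307) and 0.22 in affected rats (adjusted p = 0.0101). Hpd, an enzyme of tyrosine breakdown, stood at -0.64 and -0.73 (adjusted p = 0.00304 and 0.00129), and Hsd17b10, a mitochondrial dehydrogenase of steroids and fatty acids, at -0.78 and -1.01 (adjusted p = 0.00414 and 0.000786). In affected males Tgfb1, a growth factor of fibrosis, rose by 0.57 (adjusted p = 0.0172), but its call ended without wild type male replicate 1 or 2, with adjusted p up to 0.0632. Gpx2, a glutathione peroxidase, rose by 0.69 (adjusted p = 0.0107; 0.052 without wild type male replicate 2).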
